A study of Homo sapiens with 64 samples.

How the data were processed

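RNA was measured in 64 libraries from 4 established lung cancer lines, each treated with vehicle, MYCi975, TMP195 or both compounds for 24 hours, with 4 libraries in each of 16 groups. Per the labels' protocols, RNA was purified on columns and libraries were made with a stranded total RNA kit. The deposited table holds raw read counts per gene for 60649 genes, as whole numbers with 1 column per sample. Per the submitters' processing notes, Trimmomatic, STAR and featureCounts were used with the GRCh38 build; their versions, the annotation release and the strand setting of the counting are not stated there. The identifiers are versioned Ensembl gene IDs, of which 58337 are in GENCODE 29, from which positions were taken; symbols came from a supplied table of gene IDs and names, and 42028 have a symbol.

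Samples were matched to columns by line, treatment and replicate, with 0 columns left over. TMP195 replicate 1 of H838 carries another line's tag in 2 label fields and was grouped by its title. Each library was correlated with the mean of each line over the 2000 most variable genes to check the labels.

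Counts were scaled by TMM and filtered with filterByExpr by group in edgeR 4.0.16 (R 4.3.3). Each line had 1 quasi-likelihood fit with 4 group means, and the contrasts were each treatment against vehicle, the combination against each single agent, and the combination minus both single agents plus vehicle. Genes with a Benjamini-Hochberg adjusted p below 0.05 over the genes tested in that line were called. Adjusted p-values of genes are from this test unless another tool is named, and standard errors are the log2 fold change divided by the square root of F. Overlaps over lines were compared with those of independent lists of the same sizes. Differences between lines were tested as the interaction of line and treatment in 1 edgeR fit per treatment. CPM were computed from the deposited counts with the TMM-scaled library sizes.

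39 gene lists, the contrasts, the rule for named genes and 45 alternatives were fixed before the data were examined. Lists with at least 5 tested genes in a line were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01. P-values were adjusted over all lists, lines and the treatments against vehicle together, and the tests were repeated with a correlation estimated from the data, which is given as a p-value beside each list. Members were counted as called over all genes and adjusted over the list alone. The lists described in the text were picked after their results were seen. Named genes are the largest rises and falls among genes called in all 4 lines or in 3, the 2 largest rises and falls per line at a mean of 5 CPM or more, up to 4 members of each described list, and the targets. For the combination against single agents they are the largest changes among genes called in the most lines. Clone, locus, pseudogene and small RNA names were passed over, and some genes that the rule gives are not described.

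Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, the replicate number as a block, 1 fit of all 64 libraries, scaling without mitochondrial and abundant non-coding RNA, leaving out each replicate number and each library, and fry for the lists. The fit with a term for library batch, the fits within batches and the list tests of differences between lines were chosen after seeing the data. The batches were set from the counts of overlapping genes, column names and the share of mitochondrial ribosomal RNA, as 36 libraries (first), 7 overlap-counted libraries of H460 and a second batch; the batch term kept the 16 libraries of replicate 4 and the 5 others of the second batch apart. Replicate numbers were checked by the correlation of same-numbered libraries' deviations from their group means. The numbers were taken to pair the samples where every correlation was above 0.1. This held for all comparisons in H1755 (lowest 0.407), for MYCi975 and TMP195 against vehicle in H460 (lowest 0.903 and 0.917) and H1703 (0.139 and 0.159), and in H838 for TMP195 against vehicle (0.126), combination against vehicle (0.158) and combination against TMP195 (0.105). The labels state no shared day or culture behind these numbers. Same-numbered libraries often shared a library batch, as in H460, and a batch can give such correlations too. The rule therefore cannot tell pairing from batch.

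The fits were tested on simulated data for MYCi975 against vehicle, with 200 changed genes per line. Of 100 genes changed by 1 on the log2 scale the fit of group means recovered 17 in H460, 48 in H838, 59 in H1703 and 42 in H1755, and of 100 changed by 0.5, 0, 10, 16 and 6. With the batch term it recovered 67, 65, 73 and 74, and 49, 41, 54 and 48. This does not rank the fits. False calls were 0 of 17, 2 of 60, 5 of 80 and 5 of 53 without the batch term and 6 of 122, 9 of 115, 10 of 137 and 7 of 129 with it. Figures used matplotlib 3.10.9 in Python 3.11.15.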

Results

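Total RNA was sequenced from 4 established human non-small cell lung cancer lines, H460, H838, H1703 and H1755. Each line received vehicle (DMSO), 5 µM MYCi975 (a small molecule inhibitor of the transcription factor MYC), 25 µM TMP195 (an inhibitor of class IIa histone deacetylases, HDAC4, HDAC5, HDAC7 and HDAC9), or both compounds for 24 hours. Each of the 16 groups held 4 replicates, giving 64 libraries with 17352066 to 34236552 counted reads each. Every library correlated best with its own line. Over the 2000 most variable genes the lowest mean correlation with libraries of its own line was 0.668. The highest with those of another line was 0.502. The labels do not say whether replicates were separate cultures, so all p-values measure the spread between these samples. Fold changes are given on the log2 scale with their standard error and come from 4 libraries against 4.

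Libraries also differed in ways the treatments do not explain. In H460, 7 libraries (replicates 1 and 2 of vehicle, MYCi975 and TMP195, and replicate 1 of the combination) held counts for EEF1G of 639 to 759 CPM (counts relative to the library total), against 0 in the other 57 libraries, and for other genes that overlap a neighbour. In H838, TMP195 replicates 1 to 3 and MYCi975 replicate 3, and in H1703 combination replicate 2, shared with all replicates 4 a lower share of mitochondrial ribosomal RNA. That share was 5.12 to 10.7% in these 21 libraries, 10.1 to 19.1% in 36 others and 13.9 to 16.4% in the 7 H460 libraries. Counts with a term for these library batches are therefore given beside those without.

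**Figure D1:**
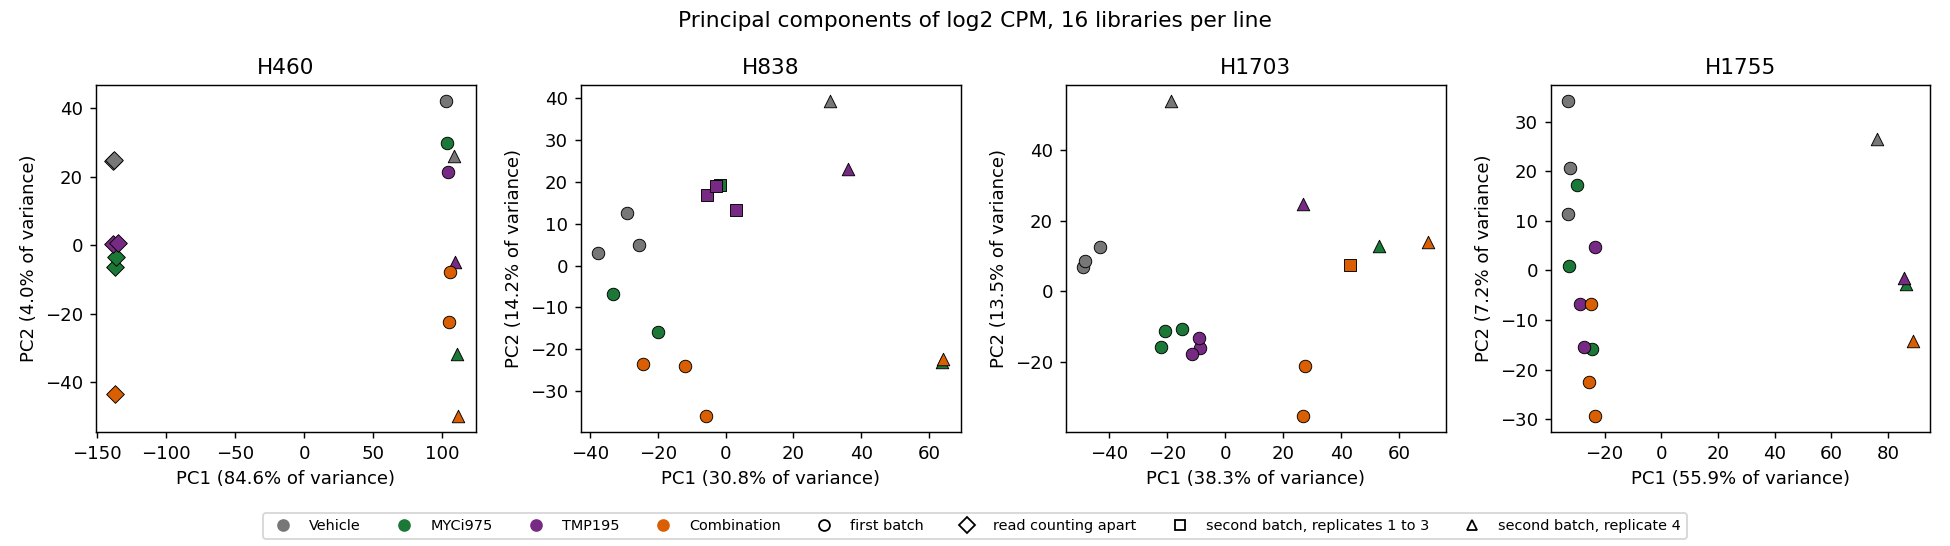
Principal components of log2 CPM within each line, with the percent of variance on each axis; each point is 1 library, coloured by treatment and shaped by library batch. The first component took 84.6% of the variance in H460, where it parted the 7 libraries from the other 9, and 30.8% in H838, 38.3% in H1703 and 55.9% in H1755.

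The RNA of the inhibitors' targets was examined first. Both compounds act on proteins, so these levels do not check the labels. HDAC5 (chromosome 17, 44076746 to 44123702, GRCh38) rose with the combination in all 4 lines, by 1.05 ± 0.11 in H460, 0.52 ± 0.12 in H838, 1.01 ± 0.16 in H1703 and 2.02 ± 0.10 in H1755 (adjusted p = 4.81e-05, 0.0245, 1.12e-04 and 7.09e-08). With TMP195 alone it rose by 0.66 ± 0.10 in H460, 0.91 ± 0.16 in H1703 and 1.45 ± 0.10 in H1755, and with MYCi975 alone by 0.78 ± 0.16 in H1703 and 1.53 ± 0.10 in H1755. In H1755 its mean level was 17.5 ± 1.7 CPM (SD, n = 4) in vehicle and 71.3 ± 5.49 CPM in the combination. MYC (chromosome 8, 127735434 to 127741434) rose by 0.43 ± 0.12 in H1703 and fell by 0.44 ± 0.09 in H1755 with the combination (adjusted p = 0.00849 and 0.0203). Its values were -0.18 ± 0.11 in H460 and -0.44 ± 0.17 in H838. With the single agents MYC passed the threshold in no line without the batch term. When it was added, H1755 passed for MYCi975 (-0.37 ± 0.08, adjusted p = 0.0132) and TMP195 (-0.37 ± 0.08, 0.00677), and H1703 for MYCi975 (0.31 ± 0.09, 0.0127). HDAC4 (chromosome 2, 239048168 to 239401654) fell with the combination by 0.35 ± 0.09 in H460 and 0.25 ± 0.09 in H1703. HDAC9 (chromosome 7, 18086949 to 19002416) rose by 0.35 ± 0.13 in H1703 (adjusted p = 0.0374). HDAC7 (chromosome 12, 47782722 to 47833132) had values between 0.00 and 0.33 with the combination and did not pass the threshold without the batch term.

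The response to MYCi975 was measured against vehicle in each line. VLDLR, a lipoprotein receptor gene, was the 1 gene that rose in 3 lines in the fit of group means (82 rose in at least 3 with the batch term and 162 with replicates as blocks), by 1.75 ± 0.24 in H460, 0.43 ± 0.12 in H1703 and 1.19 ± 0.19 in H1755 (adjusted p = 0.00962, 0.0336 and 0.0346). In H838 its value was 0.87 ± 0.33. In H460 CHAC1, a glutathione-degrading enzyme, rose by 4.0 ± 0.55 and ADM2, a peptide hormone, by 3.78 ± 0.54. TXNIP, an inhibitor of glucose uptake, and its relative ARRDC4 fell in H460, by 2.62 ± 0.22 and 1.54 ± 0.16. In H1703 GDF15, a secreted stress factor, rose by 3.06 ± 0.59 and BEX2 by 2.46 ± 0.24, while CDKN2C, a cyclin-dependent kinase inhibitor, fell by 1.54 ± 0.39. In H1755 the cytokine IL24 rose by 1.44 ± 0.25 and SNAI2, a transcription factor of mesenchymal cells, fell by 0.81 ± 0.12.

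Targets of ATF4, the transcription factor of the integrated stress response, were higher with MYCi975, with median changes of 0.83 in H460, 0.77 in H838, 0.45 in H1703 and 0.29 in H1755. The test of the list against other genes gave adjusted p = 5.04e-37, 7.99e-24, 3.28e-21 and 1.29e-11; adjusted p = 0.119, 0.236, 0.00144 and 0.285 with an estimated correlation, so that the call held in H1703 alone. Members past the threshold over all genes numbered 20 of 48 in H460, 0 of 48 in H838, 27 of 47 in H1703 and 2 of 47 in H1755 (40, 32, 38 and 4 adjusted over the list alone). DDIT4, an inhibitor of mTORC1, rose by 1.15 ± 0.13 in H460 and 1.13 ± 0.14 in H1703. SESN2 rose by 1.38 ± 0.31 and 1.19 ± 0.14 in the same lines, and CHAC1 in H1703 by 0.94 ± 0.17.

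Cell cycle genes were lower. Mitotic genes had medians of -0.18 in H460, -0.36 in H838, -0.63 in H1703 and -0.17 in H1755 (adjusted p = 4.17e-11, 1.08e-16, 4.38e-34 and 5.88e-07; adjusted p = 0.276, 0.413, 0.0284 and 0.599 with an estimated correlation). Past the threshold over all genes were 2 of 45 in H460, 0 of 45 in H838, 39 of 45 in H1703 and 0 of 45 in H1755 (2, 0, 41 and 0 adjusted over the list alone). Examples are the mitotic cyclin CCNB1, which fell by 0.34 ± 0.07 in H460 and 0.65 ± 0.10 in H1703, and the ubiquitin-conjugating enzyme UBE2C, which fell by 0.34 ± 0.06 and 0.50 ± 0.12. The kinesin KIF20A and the kinase PLK1 fell in H1703 by 0.91 ± 0.11 and 0.61 ± 0.10. S-phase genes had medians of -0.14 in H460, -0.24 in H838, -0.46 in H1703 and -0.17 in H1755 (adjusted p = 2.18e-08, 5.62e-10, 1.49e-20 and 3.6e-09; adjusted p = 0.428, 0.555, 0.276 and 0.533 with an estimated correlation). In number, 23 of 52 fell in H1703 (41 adjusted over the list alone) and 0 passed elsewhere. Among these, RRM2, a subunit of ribonucleotide reductase, fell by 0.93 ± 0.15 in H1703, the origin recognition gene ORC1 by 0.91 ± 0.20 and the replication gene GINS1 by 0.78 ± 0.20. Replication-dependent histones had medians of -0.21 in H460, -0.57 in H838, -0.46 in H1703 and -0.23 in H1755 (adjusted p = 3.52e-04, 1.28e-09, 7.27e-06 and 4.65e-05; adjusted p = 0.669, 0.507, 0.612 and 0.672 with an estimated correlation). H1-5 in H1703 was the 1 member past the threshold, at -0.80 ± 0.20, over all genes and adjusted over the list alone. Histone genes share near-identical sequences, so reads can be split between them.

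MYC targets of ribosome biogenesis were lower by small amounts, with medians of -0.13 in H460, -0.13 in H838, -0.13 in H1703 and -0.16 in H1755 (adjusted p = 4.54e-06, 2.16e-05, 0.00123 and 4.91e-09; adjusted p = 0.285, 0.58, 0.492 and 0.327 with an estimated correlation). Of 55 members, 4 fell in H1703, both over all genes and adjusted over the list alone: the ribosome assembly genes MRTO4 (-0.40 ± 0.10) and GRWD1 (-0.38 ± 0.10), TMEM97 (-0.48 ± 0.09) and ODC1, the first enzyme of polyamine synthesis (-0.38 ± 0.10). Cholesterol synthesis genes were lower in 3 lines and higher in H1755, with medians of -0.32 in H460, -0.15 in H838, -0.32 in H1703 and 0.15 in H1755 (adjusted p = 1.45e-09, 5.95e-04, 8.85e-09 and 0.00432; adjusted p = 0.285, 0.0743, 0.026 and 0.536 with an estimated correlation). In H1703 10 of 24 fell (13 adjusted over the list alone), among them EBP by 0.76 ± 0.14 and IDI1 by 0.42 ± 0.09. In the other lines 0 passed either way. Heat shock genes had medians of -0.21 in H460, -0.23 in H838, -0.49 in H1703 and -0.11 in H1755 (adjusted p = 1.83e-04, 0.00583, 8.02e-07 and 0.0582, the last 0.00206 with replicates as blocks; adjusted p = 0.467, 0.633, 0.353 and 0.672 with an estimated correlation). In H1703 6 of 19 fell (13 adjusted over the list alone). Chaperones among them were HSP90AA1 at -0.77 ± 0.20, DNAJA1 at -0.76 ± 0.22, HSP90AB1 at -0.56 ± 0.14 and CHORDC1 at -0.54 ± 0.13.

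By count, edgeR called 231 genes in H460 (215 higher, 16 lower), 2116 in H1703 (1257 and 859), 13 in H1755 (12 and 1) and 0 in H838, where 1541 genes had an unadjusted p below 0.05 and DESeq2 called 42. Adding the batch term gave 1592 in H460, 73 in H838, 5097 in H1703 and 488 in H1755. Within the first batch alone, which in H460 holds 1 library each of vehicle, MYCi975 and TMP195 and 2 of the combination, they were 1 in H460, 6 in H838, 2383 in H1703 and 113 in H1755. With replicate numbers as blocks, where these were taken to pair the samples, edgeR called 1384 in H460, 5328 in H1703 and 1866 in H1755.

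**Figure D2:**
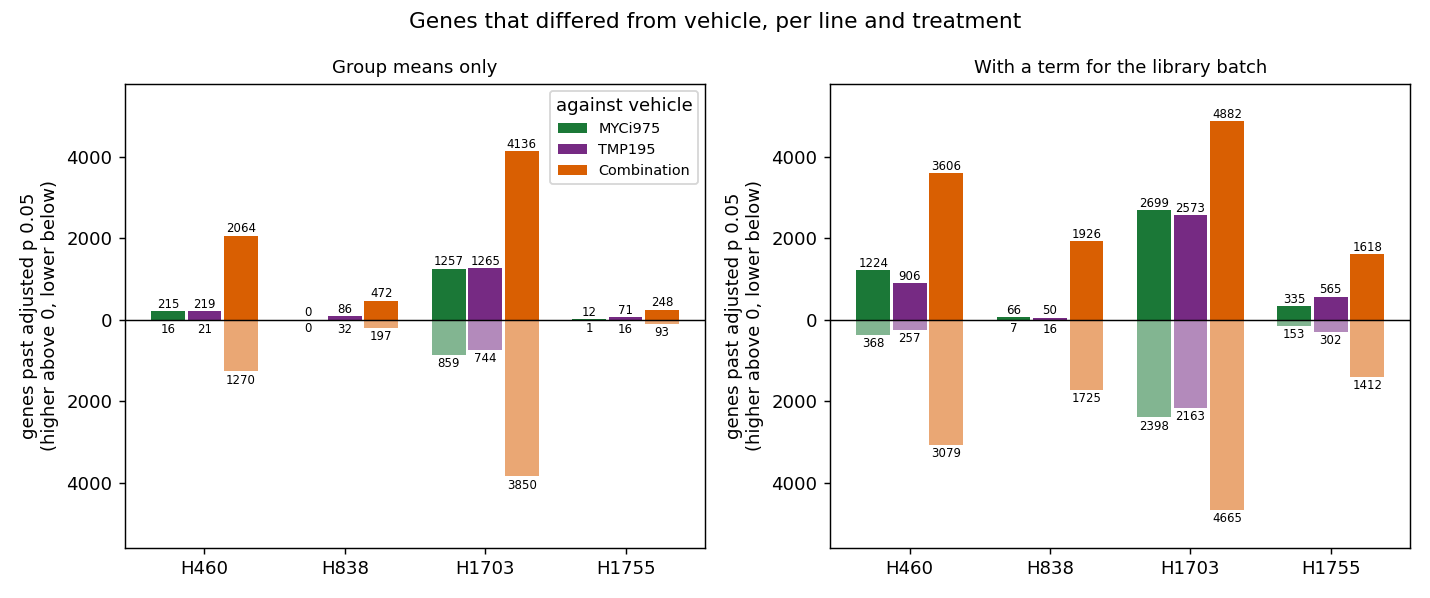
Number of genes past an adjusted p of 0.05 for each treatment against vehicle in each line, higher genes above 0 and lower genes below, from the fit of group means and from the fit with a term for library batch. The combination in H1703 gave the tallest bars, 4136 higher and 3850 lower genes in the fit of group means.

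The response to TMP195 was measured in the same way. DNAJB9, a co-chaperone of the endoplasmic reticulum (chromosome 7, 108569568 to 108574850), rose in all 4 lines, by 0.89 ± 0.12 in H460, 1.32 ± 0.15 in H838, 1.2 ± 0.13 in H1703 and 1.30 ± 0.23 in H1755 (adjusted p = 0.00446, 0.00134, 2.63e-05 and 0.0209). EDEM2, a gene of glycoprotein degradation, rose by 0.52 ± 0.10 in H460, 0.90 ± 0.18 in H838, 0.35 ± 0.10 in H1703 and 0.75 ± 0.11 in H1755. STT3A, a subunit of oligosaccharyltransferase, rose by 0.39 ± 0.08 in H460, 0.40 ± 0.08 in H838, 0.31 ± 0.08 in H1703 and 0.51 ± 0.10 in H1755. These were the 3 genes called in all lines in the fit of group means, where independent lists of these sizes would share 0.000213. STT3A had an adjusted p of 0.0938 in H838 once the batch term was added, and WWC1, described next, 0.192. Rising in 3 lines were the disulfide isomerase AGR2 (H460 1.46 ± 0.13, H1703 1.77 ± 0.43, H1755 1.42 ± 0.27), VLDLR (H460 1.11 ± 0.23, H1703 0.55 ± 0.12, H1755 1.39 ± 0.19), the coat protein gene SEC24D and the calcium-binding gene NUCB2. SEC24D and NUCB2 were at 0.49 ± 0.09 and 0.73 ± 0.14 in H460, 1.39 ± 0.26 and 1.04 ± 0.15 in H838, and 0.81 ± 0.11 and 0.69 ± 0.10 in H1703. IGFBP3, which binds insulin-like growth factors, fell by 1.17 ± 0.10 in H460, 1.16 ± 0.18 in H838 and 0.48 ± 0.12 in H1703. WWC1, of the Hippo pathway, fell by 0.53 ± 0.09, 0.52 ± 0.11 and 0.62 ± 0.17.

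Other genes passed in fewer lines. In H460 CHAC1 rose by 3.31 ± 0.54 and ADM2 by 3.25 ± 0.53, while the splicing factor RBM20 and the keratin KRT80 fell by 0.75 ± 0.14 and 0.75 ± 0.16. In H838 the transcription factor BHLHA15 rose by 2.61 ± 0.36 and the integrin ITGA2 by 1.13 ± 0.19, and BCAM and GLIS2 fell by 1.19 ± 0.18 and 1.10 ± 0.18. ITGA2 and GLIS2 had adjusted p = 0.0618 and 0.137 with the batch term. In H1703 GDF15 rose by 3.03 ± 0.60 and the neurotrophin receptor NGFR by 2.98 ± 0.32, and STARD4, a sterol carrier, fell by 1.92 ± 0.22. In H1755 the nuclear receptor NR4A1 rose by 1.98 ± 0.37 and BHLHA15 by 1.78 ± 0.36, and ID4 and SMAD9, of BMP signalling, fell by 1.5 ± 0.25 and 1.21 ± 0.19.

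Chaperones of the endoplasmic reticulum and genes of the unfolded protein response were higher with TMP195, with medians of 0.47 in H460, 0.39 in H838, 0.16 in H1703 and 0.47 in H1755 (adjusted p = 8.83e-20, 1.49e-14, 2.77e-05 and 1.68e-30; adjusted p = 0.00387, 0.0982, 0.0735 and 0.0265 with an estimated correlation). Past the threshold over all genes were 10 of 27 in H460, 6 of 27 in H838, 10 of 27 in H1703 and 7 of 27 in H1755 (17, 18, 11 and 19 adjusted over the list alone). Besides DNAJB9, the chaperone HYOU1 rose by 0.70 ± 0.11 in H460, 0.74 ± 0.09 in H1703 and 0.66 ± 0.11 in H1755. PDIA4, a disulfide isomerase, rose by 0.72 ± 0.08 in H460, 0.57 ± 0.11 in H838 and 0.77 ± 0.07 in H1755, and had a value of 0.07 ± 0.14 in H1703. XBP1, a transcription factor of this response, rose by 0.80 ± 0.18 in H460 and 0.87 ± 0.10 in H1703. Targets of ATF4 had medians of 0.64 in H460, 0.16 in H838, 0.55 in H1703 and 0.27 in H1755 (adjusted p = 1.61e-29, 0.408, 7.42e-29 and 4.76e-12; adjusted p = 0.163, 0.937, 8.35e-04 and 0.276 with an estimated correlation). Members that rose numbered 11 of 48 in H460, 0 of 48 in H838, 35 of 47 in H1703 and 3 of 47 in H1755 (34, 0, 39 and 4 adjusted over the list alone), with DDIT4 at 1.03 ± 0.13 in H460 and 1.92 ± 0.14 in H1703.

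Cholesterol synthesis genes went opposite ways, with medians of 0.46 in H460, -0.17 in H838, -0.64 in H1703 and -0.12 in H1755 (adjusted p = 8.54e-14, 4.96e-04, 7.77e-22 and 0.00142; adjusted p = 0.21, 0.0735, 0.00133 and 0.484 with an estimated correlation). In H460 3 of 24 rose (14 adjusted over the list alone), and in H1703 18 of 24 fell (20 adjusted over the list alone). INSIG1, a regulator of SREBP, was at -1.42 ± 0.13 in H1703 and 0.67 ± 0.30 in H460, the latter with adjusted p = 0.478. The difference of the list between these lines had adjusted p = 8.92e-51; adjusted p = 7.07e-06 with an estimated correlation. Mitotic genes had medians of -0.14 in H460, -0.22 in H838, -0.60 in H1703 and -0.16 in H1755 (adjusted p = 5.23e-08, 0.00163, 2.36e-35 and 1.73e-05; adjusted p = 0.387, 0.745, 0.0283 and 0.654 with an estimated correlation). Past the threshold, 36 of 45 fell in H1703 (41 adjusted over the list alone). Among them, KIF20A fell by 1.16 ± 0.11, BIRC5 by 0.88 ± 0.15 and MKI67 by 0.87 ± 0.15. S-phase genes had medians of -0.13 in H460, -0.17 in H838, -0.30 in H1703 and -0.19 in H1755 (adjusted p = 1.42e-07, 0.0305, 7.22e-10 and 2.06e-08; adjusted p = 0.447, 0.854, 0.467 and 0.554 with an estimated correlation). In number, 7 of 52 fell in H1703 (22 adjusted over the list alone), such as E2F8 by 0.59 ± 0.16. Aryl hydrocarbon receptor targets, which include the xenobiotic enzymes CYP1A1 and CYP1B1, had medians of 0.83 in H460, -0.11 in H838, 0.24 in H1703 and 0.34 in H1755 (adjusted p = 8.18e-08, 0.869, 0.322 and 5.93e-05; adjusted p = 0.138, 0.958, 0.728 and 0.0283 with an estimated correlation). In H838 the mean, -0.06, and the median were below 0 while the test pointed up. CYP1A1 rose by 1.79 ± 0.25 in H1755, CYP1B1 by 0.90 ± 0.11 and NQO1 by 0.54 ± 0.08 in H460. In order of lines, 2, 0, 0 and 1 members rose over all genes and 6, 1, 0 and 4 adjusted over the list alone. SLC7A5, an amino acid transporter, fell in H838 by 0.52 ± 0.11 (-0.21 ± 0.09, adjusted p = 0.498, with the batch term).

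The counts were 240 genes in H460 (219 higher, 21 lower), 118 in H838 (86 and 32), 2009 in H1703 (1265 and 744) and 87 in H1755 (71 and 16). The batch term gave 1163 in H460, 66 in H838, 4736 in H1703 and 867 in H1755. As blocks, replicates gave 1093 in H460, 4961 in H1703, 2120 in H1755 and 1538 in H838, which reads batch and treatment together. Within the first batch alone they were 56 in H460, 3664 in H1703 and 353 in H1755. In H838 that batch holds no TMP195 library, and the second batch alone gave 0 (edgeR; 1535 genes at an unadjusted p below 0.05; DESeq2 called 44). With 1 vehicle library in that batch, this 0 does not test the 118 calls. Without TMP195 replicate 1 of H838, whose cell line tag names another line, H838 had 21; without TMP195 replicates 2 or 3 it had 28 or 20, and without vehicle replicates 1, 2 or 3 it had 37, 24 or 29, so the lower count is not particular to that library. In H838, 33 of the 118 called genes were also called with the batch term. There the term rests on 1 MYCi975 library and on the replicates 4.

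**Figure D3:**
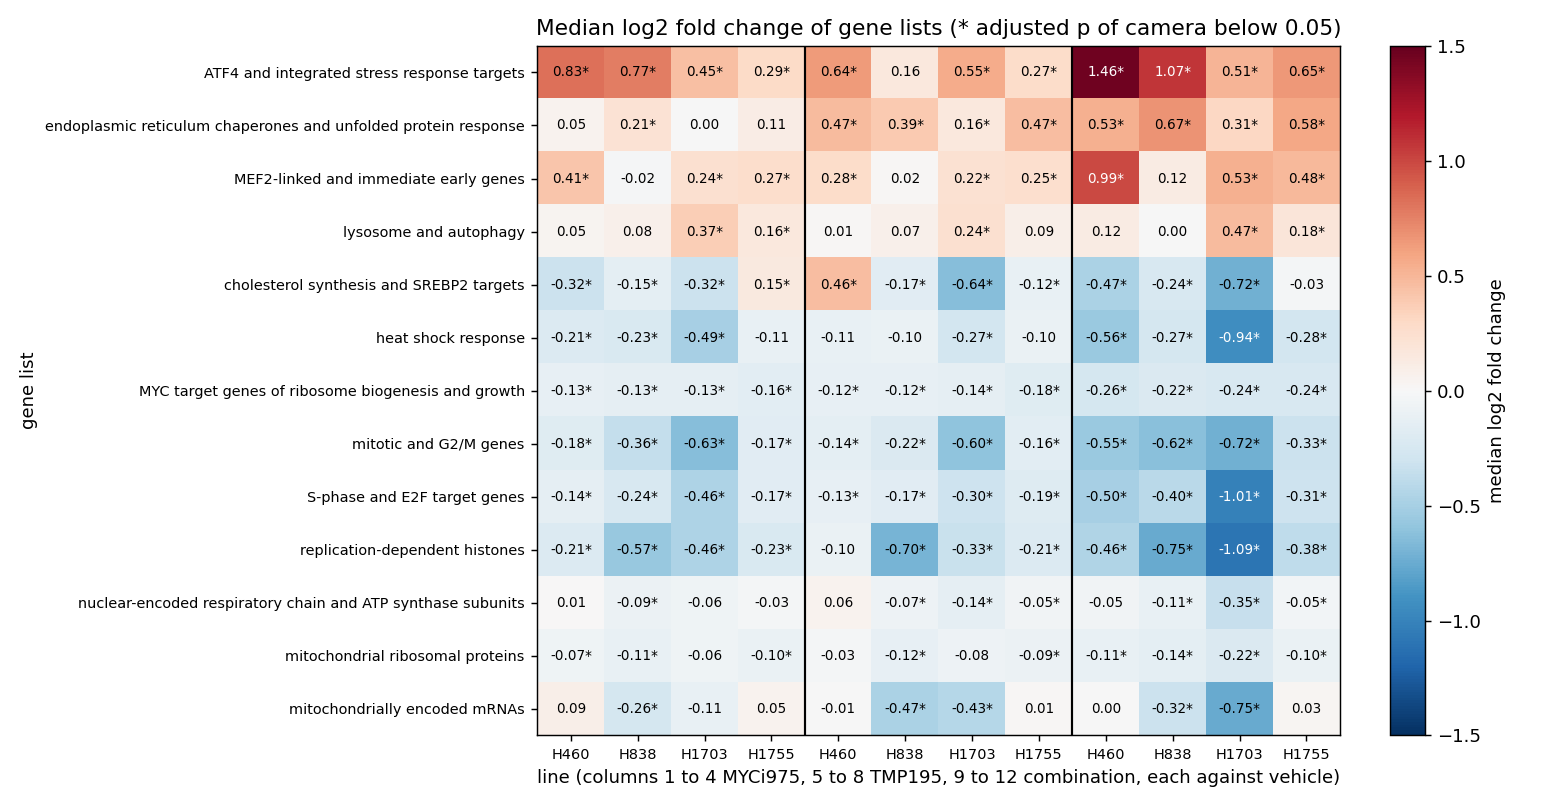
Median log2 fold change of the members of 13 described lists, by treatment against vehicle and line; red is higher, blue is lower, and an asterisk marks an adjusted p below 0.05 in the test of the list against other genes with a preset correlation. ATF4 targets reached a median of 1.46 with the combination in H460, and replication-dependent histones -1.09 in H1703.

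The combination was compared with vehicle in each line. ALDH1L2, a mitochondrial folate enzyme (chromosome 12, 105019784 to 105084577), was among the genes that rose in all 4 lines, by 3.12 ± 0.40 in H460, 2.96 ± 0.49 in H838, 0.92 ± 0.21 in H1703 and 2.11 ± 0.23 in H1755 (adjusted p = 1.87e-04, 0.00389, 0.00214 and 2.12e-04). In H460 its mean level was 29.6 ± 2.09 CPM in vehicle and 258 ± 57.5 CPM in the combination (SD, n = 4). BHLHA15, a transcription factor of secretory cells, rose by 2.58 ± 0.42 in H460, 3.41 ± 0.36 in H838, 1.00 ± 0.32 in H1703 and 1.77 ± 0.36 in H1755. The hormone STC2 rose by 2.54 ± 0.20 in H460, 2.29 ± 0.38 in H838, 1.83 ± 0.31 in H1703 and 1.30 ± 0.24 in H1755. PCK2, a mitochondrial gluconeogenic enzyme, rose by 2.80 ± 0.40 in H460, 2.52 ± 0.58 in H838, 1.13 ± 0.07 in H1703 and 1.06 ± 0.20 in H1755. DDIT4 rose by 1.87 ± 0.13 in H460, 2.26 ± 0.29 in H838, 1.93 ± 0.14 in H1703 and 1.04 ± 0.20 in H1755. DNAJB9 rose by 1.15 ± 0.13 in H460, 1.80 ± 0.16 in H838, 1.78 ± 0.13 in H1703 and 1.43 ± 0.23 in H1755, and the actin-binding gene ABLIM3 by 3.39 ± 0.49 in H460, 1.40 ± 0.33 in H838, 1.88 ± 0.52 in H1703 and 0.62 ± 0.10 in H1755. BCAN-AS2, an antisense gene, had values of 0.83, 1.69, 2.07 and 0.64.

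Of the 5 genes that fell in all 4 lines, IGFBP3 fell by 0.84 ± 0.10 in H460, 1.02 ± 0.18 in H838, 0.96 ± 0.12 in H1703 and 1.03 ± 0.20 in H1755. TMEM19 had values of -0.47 ± 0.11 in H460, -0.63 ± 0.11 in H838, -1.0 ± 0.13 in H1703 and -0.77 ± 0.17 in H1755. The condensin subunit NCAPD2 was at -0.72 ± 0.10 in H460, -0.53 ± 0.11 in H838, -1.04 ± 0.09 in H1703 and -0.55 ± 0.13 in H1755. The phosphatase PPP1CC was at -0.39 ± 0.07 in H460, -0.55 ± 0.14 in H838, -0.70 ± 0.10 in H1703 and -0.46 ± 0.10 in H1755. PAICS, an enzyme of purine synthesis, was at -0.25 ± 0.06 in H460, -0.37 ± 0.10 in H838, -0.67 ± 0.10 in H1703 and -0.38 ± 0.08 in H1755. CDKN2C fell in 3 lines, to -3.02 ± 0.43 in H1703. SMAD6, an inhibitor of BMP signalling, and the protease gene ADAMTS3 also fell in 3, with -1.25 ± 0.16 in H838 and -1.55 ± 0.30 in H460. In H460 CHAC1 rose by 5.46 ± 0.59 and ADM2 by 5.03 ± 0.57, and CPLX2 and GPR22 fell by 1.86 ± 0.39 and 1.81 ± 0.24. In H838 PHGDH, the first enzyme of serine synthesis, rose by 3.12 ± 0.63, and NPTX1 and the DNA methyltransferase DNMT3B fell by 1.12 ± 0.28 and 1.01 ± 0.24. In H1703 GDF15 and NGFR rose by 4.13 ± 0.59 and 4.09 ± 0.33, and FAM222A fell by 2.98 ± 0.38. In H1755 NR4A1 and the synaptic gene UNC13A rose by 2.84 ± 0.38 and 2.45 ± 0.53, and ID4 and ID2 fell by 1.83 ± 0.26 and 1.78 ± 0.36.

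**Figure D4:**
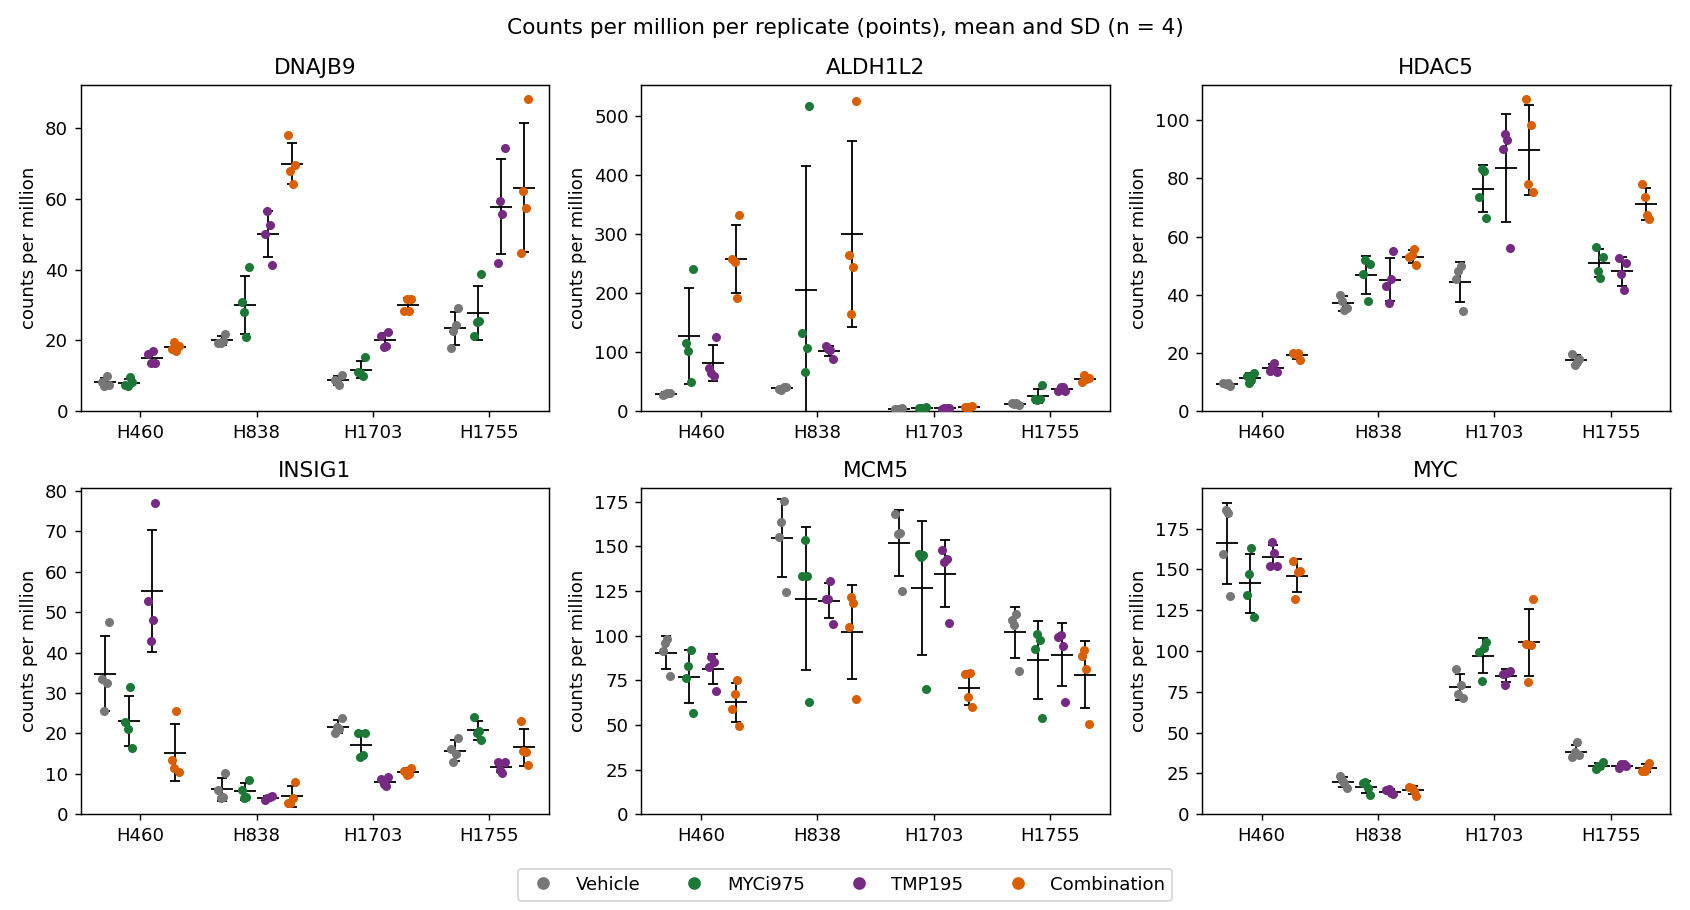
CPM of DNAJB9, ALDH1L2, HDAC5, INSIG1, MCM5 and MYC in each library (points), by line and treatment, with the mean and SD of 4 libraries. DNAJB9 was higher with TMP195 than with vehicle by 0.89 to 1.32 (log2) over the 4 lines.

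Stress response genes were higher. ATF4 targets had medians of 1.46 in H460, 1.07 in H838, 0.51 in H1703 and 0.65 in H1755 (adjusted p = 5.04e-37, 7.15e-26, 3.23e-11 and 4.49e-23; adjusted p = 0.119, 0.218, 0.0167 and 0.119 with an estimated correlation). Past the threshold, 44 of 48 in H460, 26 of 48 in H838, 32 of 47 in H1703 and 14 of 47 in H1755 rose (46, 37, 35 and 28 adjusted over the list alone). The tryptophan tRNA synthetase WARS1 rose by 1.84 ± 0.22 in H460, 1.44 ± 0.33 in H838, 0.77 ± 0.08 in H1703 and 0.91 ± 0.22 in H1755. Endoplasmic reticulum genes had medians of 0.53 in H460, 0.67 in H838, 0.31 in H1703 and 0.58 in H1755 (adjusted p = 1.49e-09, 5.1e-25, 0.00126 and 4.61e-21; adjusted p = 0.0284, 0.0304, 0.146 and 0.0618 with an estimated correlation). In number, 16 of 27 in H460, 20 of 27 in H838, 14 of 27 in H1703 and 12 of 27 in H1755 rose (18, 25, 14 and 16 adjusted over the list alone). HYOU1 rose by 0.85 ± 0.11 in H460, 0.73 ± 0.14 in H838, 0.70 ± 0.09 in H1703 and 0.79 ± 0.11 in H1755. SELENOS rose by 0.32 ± 0.09 in H460, 0.71 ± 0.11 in H838, 0.79 ± 0.12 in H1703 and 0.65 ± 0.11 in H1755, and the chaperone HSP90B1 by 0.64 ± 0.12 in H460, 0.55 ± 0.11 in H838, 0.32 ± 0.07 in H1703 and 0.71 ± 0.11 in H1755. MEF2-linked and immediate early genes had medians of 0.99 in H460, 0.12 in H838, 0.53 in H1703 and 0.48 in H1755 (adjusted p = 2.83e-08, 0.692, 0.0038 and 9.36e-09; adjusted p = 0.185, 0.928, 0.276 and 0.0735 with an estimated correlation). Over all genes, 11 of 26 in H460, 0 of 25 in H838, 13 of 25 in H1703 and 7 of 25 in H1755 were up (13, 2, 15 and 11 adjusted over the list alone) and 0, 2, 2 and 0 down. MEF2D rose by 0.59 ± 0.07 in H460, 0.65 ± 0.10 in H1703 and 0.91 ± 0.19 in H1755. ATF3, which is also an ATF4 target, rose by 2.90 ± 0.29 in H460 and 1.94 ± 0.21 in H1703, and the phosphatase DUSP5 by 1.96 ± 0.35 in H1703 and 1.74 ± 0.28 in H1755.

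Proliferation genes were lower in all 4 lines by the list tests with a preset correlation. S-phase genes had medians of -0.50 in H460, -0.40 in H838, -1.01 in H1703 and -0.31 in H1755 (adjusted p = 6.71e-23, 1.29e-11, 7.03e-24 and 8.92e-13; adjusted p = 0.134, 0.516, 0.228 and 0.454 with an estimated correlation). Past the threshold, 39 of 52 in H460, 1 of 52 in H838, 49 of 52 in H1703 and 2 of 52 in H1755 fell (43, 1, 51 and 7 adjusted over the list alone). The transcription factor E2F2 fell by 0.77 ± 0.17 in H460, 0.57 ± 0.13 in H838 and 1.71 ± 0.20 in H1703, and thymidine kinase TK1 and GINS2 in H1703 by 1.98 ± 0.26 and 1.70 ± 0.21. Mitotic genes had medians of -0.55 in H460, -0.62 in H838, -0.72 in H1703 and -0.33 in H1755 (adjusted p = 5.78e-21, 2.55e-19, 1.74e-20 and 2.76e-11; adjusted p = 0.119, 0.353, 0.0884 and 0.47 with an estimated correlation). In number, 32 of 45 in H460, 9 of 45 in H838, 38 of 45 in H1703 and 0 of 45 in H1755 fell (39, 40, 39 and 0 adjusted over the list alone). KIF20A fell by 1.04 ± 0.13 in H460, 0.91 ± 0.22 in H838 and 1.24 ± 0.11 in H1703, and the kinase AURKA by 0.76 ± 0.14, 0.80 ± 0.21 and 0.94 ± 0.12. Replication-dependent histones had medians of -0.46 in H460, -0.75 in H838, -1.09 in H1703 and -0.38 in H1755 (adjusted p = 8.35e-06, 3.93e-08, 7.86e-11 and 3.26e-05; adjusted p = 0.599, 0.554, 0.458 and 0.67 with an estimated correlation). Over all genes, 9 of 49 in H460, 1 of 43 in H838, 36 of 47 in H1703 and 0 of 50 in H1755 were down (10, 1, 38 and 0 adjusted over the list alone), such as H2AC12 at -2.22 ± 0.30 and H2AC4 at -2.02 ± 0.34 in H1703. MYC targets had medians of -0.26 in H460, -0.22 in H838, -0.24 in H1703 and -0.24 in H1755 (adjusted p = 1.02e-06, 5.45e-06, 3.38e-04 and 2.81e-10; adjusted p = 0.276, 0.538, 0.456 and 0.285 with an estimated correlation). In number, 12 of 55 in H460, 0 of 55 in H838, 23 of 55 in H1703 and 1 of 55 in H1755 fell (15, 0, 24 and 6 adjusted over the list alone) and 3 rose in H1703. POLR1A, the largest subunit of RNA polymerase I, fell by 0.34 ± 0.06 in H460, 0.38 ± 0.07 in H1703 and 0.38 ± 0.09 in H1755, and the DNA glycosylase UNG by 0.75 ± 0.13 in H460 and 0.92 ± 0.14 in H1703.

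Heat shock genes had medians of -0.56 in H460, -0.27 in H838, -0.94 in H1703 and -0.28 in H1755 (adjusted p = 3.93e-07, 0.00634, 6.02e-06 and 0.00145; adjusted p = 0.323, 0.634, 0.413 and 0.493 with an estimated correlation). Past the threshold, 8 of 20 fell in H460 and 13 of 19 in H1703 (13 and 14 adjusted over the list alone). HSP90AA1 fell by 0.78 ± 0.17 and 1.49 ± 0.21, HSPH1 by 0.70 ± 0.16 and 1.12 ± 0.13 and HSPA8 by 0.54 ± 0.11 and 1.09 ± 0.16. Cholesterol synthesis genes had medians of -0.47 in H460, -0.24 in H838, -0.72 in H1703 and -0.03 in H1755 (adjusted p = 1.9e-06, 1.44e-04, 1.74e-10 and 0.405; adjusted p = 0.447, 0.0593, 0.0167 and 0.859 with an estimated correlation). In number, 9 of 24 in H460, 1 of 25 in H838, 18 of 24 in H1703 and 0 of 24 in H1755 fell (12, 3, 19 and 0 adjusted over the list alone). NSDHL fell by 0.52 ± 0.13 in H460, 0.57 ± 0.15 in H838 and 0.24 ± 0.07 in H1703, and INSIG1 and IDI1 in H1703 by 1.04 ± 0.13 and 0.89 ± 0.09.

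Of the lists of mitochondrial genes, 3 are given in full, in view of the series title. TCA cycle genes were also lower in H838 and H1703 (adjusted p = 0.0383 and 0.007, the first 0.063 with replicates as blocks; adjusted p = 0.436 and 0.473 with an estimated correlation). Factors of mitochondrial biogenesis and DNA expression were lower in H460, H838 and H1755 (adjusted p = 0.0274, 0.0317 and 0.0028; adjusted p = 0.225, 0.456 and 0.059 with an estimated correlation). The 13 mitochondrially encoded mRNAs had medians of 0.00 in H460, -0.32 in H838, -0.75 in H1703 and 0.03 in H1755 (adjusted p = 0.826, 0.0481, 0.0106 and 0.979; adjusted p = 0.969, 0.728, 0.669 and 0.992 with an estimated correlation). Of these, 8 fell in H1703 (9 adjusted over the list alone) and 1 rose in H460. In H460 the test pointed up, with a mean of 0.07, and in H1755 it pointed down with a median above 0; both missed the threshold. In H1703 MT-CO3, a cytochrome oxidase subunit, fell by 1.22 ± 0.32, MT-ATP8 by 1.19 ± 0.37, MT-ND3 by 0.83 ± 0.22 and MT-ND6 by 0.75 ± 0.20. Libraries of the second batch had a lower share of mitochondrially encoded mRNA (1.16 to 2.64%, against 1.88 to 3.49% in the first), and combination replicate 2 of H1703 belongs to it. After adding the batch term the H1703 median was -0.71 (adjusted p = 0.00251; adjusted p = 0.554 with an estimated correlation). Nuclear genes of the respiratory chain and ATP synthase had medians of -0.05 in H460, -0.11 in H838, -0.35 in H1703 and -0.05 in H1755 (adjusted p = 0.257, 0.00831, 1.81e-05 and 0.0428, the last 0.0654 with the batch term and 0.0619 with replicates as blocks; adjusted p = 0.859, 0.597, 0.586 and 0.672 with an estimated correlation). In H1703 22 of 76 fell over all genes and adjusted over the list alone, among them NDUFB3 of complex I by 1.10 ± 0.16 and ATP5MC3 of ATP synthase by 0.92 ± 0.14. ATP5MC3 also fell in H460, by 0.44 ± 0.12. Mitochondrial ribosomal proteins had medians of -0.11 in H460, -0.14 in H838, -0.22 in H1703 and -0.10 in H1755 (adjusted p = 0.0111, 7.27e-04, 0.00747 and 0.00297; adjusted p = 0.602, 0.447, 0.633 and 0.456 with an estimated correlation). Over all genes, 3, 0, 18 and 0 of 77, 76, 76 and 76 were down (2, 0, 13 and 0 adjusted over the list alone) and 1 and 3 up in H460 and H1703. MRPL35 fell by 0.34 ± 0.08 in H460 and 0.31 ± 0.09 in H1703.

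The combination changed 3334 genes in H460 (2064 higher, 1270 lower), 669 in H838 (472 and 197), 7986 in H1703 (4136 and 3850) and 341 in H1755 (248 and 93). With the batch term the counts were 6685 in H460, 3651 in H838, 9547 in H1703 and 3030 in H1755, and within the first batch alone 856 in H460, 1698 in H838, 7638 in H1703 and 1356 in H1755. With replicates as blocks, 3067 were called in H838 and 4900 in H1755.

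Across the 16597 genes tested in all lines, 34 rose and 5 fell with the combination in all 4, where independent lists of these sizes would share 0.11 and 0.0133. Under the batch term 347 rose and 431 fell in all 4, against 5.85 and 5.75. For MYCi975 edgeR called 0 genes in all 4 lines (DESeq2 also 0; in at least 2 lines 53 rose and 4 fell), and 9 rose with the batch term.

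To ask what each compound added to the other, the combination was compared with the single agents. Against MYCi975, DNAJB9 was higher in H460, H838 and H1703, by 1.17 ± 0.13, 1.22 ± 0.15 and 1.35 ± 0.13, and PDIA4 in H460, H838 and H1755, by 0.61 ± 0.08, 0.80 ± 0.11 and 0.78 ± 0.07. Lower than with MYCi975 in H460 and H1703 were the sliding clamp PCNA at -0.47 ± 0.10 and -0.98 ± 0.16, MCM10 at -0.54 ± 0.11 and -0.86 ± 0.18, MCM3 at -0.35 ± 0.07 and -0.76 ± 0.15 and ATAD5 at -0.39 ± 0.08 and -0.67 ± 0.14. The counts were 225 in H460, 5 in H838, 355 in H1703 and 11 in H1755. These became 2301, 76, 3001 and 199 with the batch term and 518, 89, 3568 and 168 within the first batch; with replicates as blocks H1755 had 645.

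Against TMP195, CHAC1 was higher in the combination by 2.15 ± 0.50 in H460 and 3.61 ± 0.59 in H838. KIF21B (1.99 ± 0.45 and 0.92 ± 0.26), the histone demethylase KDM7A (1.68 ± 0.33 and 1.21 ± 0.28) and PPP1R15A, a phosphatase subunit of the stress response (1.33 ± 0.23 and 1.08 ± 0.22), were higher in H460 and H1703. Lower in the same lines were PCNA (-0.55 ± 0.10 and -1.17 ± 0.16), GINS2 (-0.51 ± 0.10 and -1.13 ± 0.21) and the helicase gene MCM4 (-0.65 ± 0.12 and -1.01 ± 0.17). The counts were 830 in H460, 9 in H838 and 1014 in H1703 and 0 in H1755. There edgeR gave 415 of 20218 tested genes an unadjusted p below 0.05, under the share of about 0.05 that chance gives. DESeq2 called 1. A batch term gave 3636 in H460, 5 in H838, 3845 in H1703 and 4 in H1755. The first batch gave 2337 in H1703 and 4 in H1755, and replicates as blocks 274 in H1755 and 1467 in H838 (batch and treatment together).

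The departure of the combination from the sum of the single-agent effects was tested on the log2 scale. In H1703 30 genes departed, 9 above the sum and 21 below it. Further, 220 departed with the batch term and 117 within the first batch, but 4, 2 and 3 without replicates 1, 2 and 3, 3 without vehicle replicate 2 or 3 or TMP195 replicate 1, and 0 in 1 fit of all 64 libraries. In the other 3 lines edgeR called 0 genes. There, 634 of 21226 tested genes in H460, 1260 of 20624 in H838 and 184 of 20218 in H1755 had an unadjusted p below 0.05. Chance gives a share of about 0.05, and H460 and H1755 were below it. DESeq2 called 1, 2 and 1. With the batch term these lines had 35, 0 and 2, and with replicates as blocks H1755 had 18. No gene passed in 2 or more lines without the batch term.

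Whether the lines responded differently was tested as the interaction of line and treatment over 24980 genes for MYCi975. HDAC5 was the 1 gene whose response to MYCi975 differed (adjusted p = 0.00464). The response differed for 255 genes with TMP195 and 2163 with the combination. With the combination, genes that differed included NPTX1, at -2.86 ± 0.25 in H1703 and 0.70 ± 0.28 in H1755 (adjusted p = 1.61e-07), and PHGDH, at 3.12 ± 0.63 in H838 and -0.01 ± 0.12 in H1703 (adjusted p = 1.89e-05). With the batch term the counts were 709, 2142 and 6612 genes, and with replicates as blocks 870, 5116 and 6828.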

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

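The tests that weigh explanations here, the batch term and the list tests of differences between lines were chosen after the results were seen, while the tests of single genes between lines were planned.

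In H460, 7 libraries stood apart, with 715 genes over 8-fold higher than in the other libraries of the same treatments and 0 over 8-fold lower, among genes above 3 CPM. Of those 715 genes, 91.7% share exon positions with another gene, against 43% of genes within 2-fold. Of 6944 genes with no shared exon position, 1.67% differed over 2-fold. Other cells or culture conditions stay open, as MYCi975 moved few genes that far in H460 (71 called up, 4 down). A candidate is that reads in shared exons were counted for each gene in these libraries only. No other biological explanation was tested, and the 7 libraries span all 4 groups.

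The TMP195 response of H838 is mixed with a library batch that holds TMP195 replicates 1 to 3. Across 12887 genes, which are not independent replicates, the change of those replicates from vehicle correlated at r = 0.644 with the difference of MYCi975 replicate 3, of the same batch, from MYCi975 replicates 1 and 2. With replicate 4 of TMP195 against replicate 4 of vehicle that correlation was -0.103. The batch may thus account for part of the 118 calls, but 33 of them stayed with the batch term, such as DNAJB9 (1.37 ± 0.20, adjusted p = 0.00562 with that term). For these libraries that term rests on MYCi975 replicate 3 and on the replicates 4, so a call that stayed does not exclude the batch. Whether endoplasmic reticulum genes respond as a list stays open: they were higher with an adjusted p of 3.48e-15 with the batch term, but with an estimated correlation it was 0.306 with that term and 0.0982 without it.

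In H1755 replicate 4 stood apart in all 4 groups, with 346 genes over 2-fold higher and 482 lower than replicates 1 to 3, such as COL4A1 (mean 67.6 CPM against 1.53 to 1.55) and SORCS2 (0.889 against 23.9 to 43). A first test, that 29.9% of these genes moved the same way by over 0.5 in replicate 4 of H1703, left a shared batch undecided and was replaced after it was seen. By the second, the genes moved by a median of 0.302 (upper quartile 0.567) in H1703 and 0.364 (0.692) in vehicle and combination of H838. They were picked for their shift in H1755 (median 1.258), so smaller shifts elsewhere were likely. Whether a shared batch is part or all of the difference stays open. Cells of another of the lines are argued against by the highest median shift of such lines' genes, -0.448. Other cultures or passages stay open and were not tested.

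Among 108 groups of 4 libraries (CPM of the 5 target genes, total counts and the share of mitochondrial ribosomal RNA), 5 held a library far from the other 3 by Dixon's ratio, and chance gives about 1 in 20. HDAC4 was 33.5 CPM in replicate 4 of MYCi975 in H1703 (others 40.9 to 42.3) and 83.8 in replicate 3 of TMP195 in H1755 (99.7 to 102). HDAC5 was 56 CPM in replicate 4 of TMP195 in H1703 (90.2 to 95.4), and HDAC7 32.8 in replicate 4 of vehicle in H1703 (43.6 to 45.6). The share of mitochondrial ribosomal RNA was 10.7% in replicate 4 of vehicle in H1755 (16 to 16.5%).

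Responses differed between lines for 1 gene with MYCi975 (HDAC5, adjusted p = 0.00464), 255 with TMP195 and 2163 with the combination (edgeR interaction test). With TMP195, genes with adjusted p-values below the threshold included VLDLR (0.0411), HDAC5 (0.00746), RBM20 (0.0356), BHLHA15 (0.0461, but 0.172 with the batch term), NGFR (0.00812), STARD4 (0.0345), ID4 (0.0407), SMAD9 (0.00263), DDIT4 (0.00552), PDIA4 (0.00242), INSIG1 (0.00346), KIF20A (0.0242), NQO1 (0.0172) and MYC (0.0467). With the combination they included ALDH1L2 (1.22e-04), BHLHA15 (0.00346), STC2 (0.0449), PCK2 (0.00228), ABLIM3 (4.58e-04), DDIT4 (0.011), BCAN-AS2 (0.013), CDKN2C (3.34e-04), ADAMTS3 (0.0449), CHAC1 (2.06e-06), ADM2 (1.13e-04), GPR22 (0.011), PHGDH (1.89e-05), NPTX1 (1.61e-07), NGFR (0.00519) and FAM222A (0.00131). Further genes with the combination were NR4A1 (4.41e-04), UNC13A (0.0435), ID4 (0.00154), ID2 (0.0488), WARS1 (0.00371), E2F2 (9.45e-05), TK1 (9.73e-05), GINS2 (0.0013), HSP90AA1 (0.00106), HSPH1 (0.0219), HSPA8 (0.00986), ATP5MC3 (0.00876), NDUFB3 (0.00393), MEF2D (0.00429), ATF3 (1.61e-06), MYC (0.00454) and HDAC5 (1.9e-06).

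Of 702 comparisons of a list between 2 lines, 190 passed the threshold with a preset correlation and 13 with an estimated one. For cholesterol synthesis genes the adjusted p with an estimated correlation was 0.00525 (H460 against H1755) and 0.0124 (H1703 against H1755) with MYCi975. With TMP195 it was 0.00322, 7.07e-06 and 4.54e-04 for H460 against H838, H1703 and H1755, and 0.0221 and 0.00745 for H1703 against H838 and H1755. For lysosome and autophagy genes H1703 differed from H460 (0.0109) and H838 (0.0141) with MYCi975, from H460 (0.0178) and H1755 (0.0281) with TMP195, and from H838 (0.0178) with the combination. ATF4 targets differed between H460 and H1755 with the combination (0.0281).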

How the results depend on the processing

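The batch term, the fits within batches and those of parts of the H460 libraries were chosen after seeing the data; the other alternatives were planned. Counts of called genes depended on the setting, and values that moved over 1.5 times from the reported count are given; the cause was not tested except where fewer libraries or an added term make it plain. RLE size factors kept 32 of 33 counts within 1.5 times, scaling without mitochondrial and abundant non-coding RNA 12 of 12, and no scaling moved the share of higher calls by over 10 points. Of 812 values of named genes, a call was lost in 212 without replicate 1, 211 without replicate 2, 170 without replicate 3 and 23 without replicate 4. With no filter 43 were lost, with the batch term 6, with RLE 1 and with DESeq2 0 of those with an adjusted p. The replicate block ended 0 of their calls and, among lists, 2.

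With DESeq2 the number for MYCi975 was 687 in H460, 42 in H838 and 86 in H1755. For TMP195 there were 531 in H460, 459 in H838 and 212 in H1755, and for the combination 1281 in H838 and 782 in H1755. The fit called 767 in H460, 53 in H838, 1365 in H1703 and 79 in H1755 for the combination against MYCi975, and for the combination against TMP195 1520 in H460, 499 in H838, 2119 in H1703 and 1 in H1755. For the departure from the sum this gave 1 in H460, 2 in H838, 113 in H1703 and 1 in H1755, and for the same direction in all 4 lines 7 for TMP195 and 98 for the combination. For differences between lines calls numbered 73 for MYCi975 and 737 for TMP195. With no filter on low counts the number for MYCi975 was 91 in H460 and 35 in H838. For TMP195 the counts were 138 in H460 and 53 in H1755, and for the combination 199 in H1755. There were 81 in H460, 9 in H838, 850 in H1703 and 2 in H1755 for the combination against MYCi975, and for the combination against TMP195 383 in H460 and 149 in H838. For the same direction in all 4 lines the fit called 1 for TMP195, and for differences between lines 156 for TMP195 and 1381 for the combination. Without TMP195 replicate 1, 2 or 3 of H838 TMP195 had 21, 28 or 20 there.

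With the replicate block the number for MYCi975 was 1384 in H460, 145 in H838, 5328 in H1703 and 1866 in H1755. For TMP195 this gave 1093 in H460, 1538 in H838, 4961 in H1703 and 2120 in H1755, and for the combination 6643 in H460, 3067 in H838 and 4900 in H1755. Calls numbered 2099 in H460, 69 in H838, 4440 in H1703 and 645 in H1755 for the combination against MYCi975, and for the combination against TMP195 3562 in H460, 1467 in H838, 5002 in H1703 and 274 in H1755. For the departure from the sum the counts were 289 in H1703 and 18 in H1755, and for the same direction in all 4 lines 27 for MYCi975, 57 for TMP195 and 888 for the combination. For differences between lines there were 870 for MYCi975, 5116 for TMP195 and 6828 for the combination. The numbers were not taken to pair samples where the lowest correlation was 0.1 or less. That was so in H460 for the combination against vehicle, MYCi975 and TMP195 (-0.723, -0.704 and -0.694), in H1703 for the same (-0.088, -0.023 and -0.062), and in H838 for MYCi975 against vehicle and the combination (0.052 and 0.058). In each of these, 3 of 4 numbers correlated best with themselves. The pairs above 0.1 correlated at 0.801 to 0.942 in H460, 0.269 to 0.607 in H1703 and 0.177 to 0.717 in H838, and each low pair was of libraries from different batches, so pairing is not excluded there. With the block 2 list calls were lost, TCA cycle genes with the combination in H838 (adjusted p = 0.063) and respiratory chain genes with the combination in H1755 (0.0619), and 20 were gained. Gains include heat shock genes with MYCi975 (0.00206) and TMP195 (0.0171) in H1755 and TMP195 in H460 (0.0307), lysosome genes with TMP195 in H1755 (0.0213) and antigen presentation genes with TMP195 in H1703 (0.0266). With an estimated correlation, without the block, these 5 had adjusted p = 0.672, 0.748, 0.737, 0.285 and 0.702.

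With the batch term the number for MYCi975 was 1592 in H460, 73 in H838, 5097 in H1703 and 488 in H1755. For TMP195 the fit called 1163 in H460, 66 in H838, 4736 in H1703 and 867 in H1755, and for the combination 6685 in H460, 3651 in H838 and 3030 in H1755. This gave 2301 in H460, 76 in H838, 3001 in H1703 and 199 in H1755 for the combination against MYCi975, and for the combination against TMP195 3636 in H460, 5 in H838, 3845 in H1703 and 4 in H1755. For the departure from the sum calls numbered 35 in H460, 220 in H1703 and 2 in H1755, and for the same direction in all 4 lines 9 for MYCi975, 13 for TMP195 and 778 for the combination. For differences between lines they were 709, 2142 and 6612 in that order.

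With the first batch alone the number for MYCi975 was 1 in H460, 6 in H838 and 113 in H1755. For TMP195 there were 56 in H460, 3664 in H1703 and 353 in H1755, and for the combination 856 in H460, 1698 in H838 and 1356 in H1755. The fit called 518 in H460, 89 in H838, 3568 in H1703 and 168 in H1755 for the combination against MYCi975, and for the combination against TMP195 128 in H460, 2337 in H1703 and 4 in H1755. For the departure from the sum this gave 117 in H1703, and for the same direction in all 4 lines 128 for the combination. For differences between lines calls numbered 104 for MYCi975. In H460 that batch has 5 libraries, so a lone library is assumed to vary like the others, and in H838 it holds no TMP195 library, so no value could be had. In the second batch of H838 vehicle and the combination have 1 library each, and among the overlap-counted libraries the combination has 1, so counts that use these rest on a lone library and do not test the others. With the second batch alone the number for TMP195 was 0 in H838. For the combination there were 0 in H838, and for the combination against MYCi975 0 in H838. The fit called 0 in H838 for the combination against TMP195. With only the 7 overlap-counted libraries the number for MYCi975 was 519 in H460. For TMP195 the counts were 448 in H460, and for the combination against MYCi975 783 in H460. For the departure from the sum there were 12 in H460. With only the other 9 libraries of H460 the number was 0 for MYCi975, 0 for TMP195 and 292 for the combination. It was 0 for the combination against each single agent. Beside these counts of 0 from edgeR, unadjusted p was below 0.05 for 1535, 2325, 380 and 3057 genes in the second batch of H838, in the order given, and DESeq2 called 44, 72, 0 and 123. In the 9 libraries of H460 these were 1117, 830, 893 and 1473, and with DESeq2 54, 49, 11 and 64, for MYCi975, TMP195 and the combination against each.

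With 1 fit of 64 libraries the number for MYCi975 was 50 in H838 and 935 in H1703. For TMP195 it was 809 in H1703, for the combination against MYCi975 14 in H838 and 31 in H1755, and against TMP195 248 in H838. For the departure from the sum it was 1 in H460 and 0 in H1703. Beside the 0 in H1703 from edgeR, 896 genes had an unadjusted p below 0.05, and DESeq2 on the 64 libraries called 17. With RLE size factors the number for differences between lines was 2 for MYCi975. With an estimated correlation lists called were 5 for MYCi975, 8 for TMP195 and 4 for the combination. With the batch term as well they were 1, 2 and 0. With fry alone they were 27 for MYCi975 and 30 for TMP195.

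The direction of 3 lists turned where a value passed the threshold before or after. In H838 with TMP195 the antigen presentation list had adjusted p = 0.906 and the respiratory chain list 0.786 with the batch term, pointing up, and 0.923 and 0.949 with an estimated correlation as well. In H1755 with MYCi975 the mitochondrially encoded mRNAs pointed up without replicate 4 (adjusted p = 0.0443, and 0.914 without replicate 3); the cause was not tested.

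Each replicate number and each library was left out in turn, and the lowest and highest counts are given, then each single library that moved a count by over 1.5 times. MYCi975 in H460 ran from 0 to 400, with 30 without Vehicle 1, 57 without Vehicle 2, 50 without Vehicle 4, 77 without MYCi975 1/4. Then it was 400 without MYCi975 3, 150 without Combo 1, 151 without Combo 2. MYCi975 in H838 ran from 0 to 11, with 1 without MYCi975 4. MYCi975 in H1703 ran from 725 to 2200, with 1303 without Vehicle 1, 1366 without Vehicle 3, 1190 without MYCi975 4. MYCi975 in H1755 ran from 1 to 113, with 2 without Vehicle 1, MYCi975 3, 1 without Vehicle 2/3/4, MYCi975 1/2, 5 without TMP195 1, Combo 2, 4 without TMP195 2/3, 6 without Combo 3. TMP195 in H460 ran from 1 to 413, with 94 without Vehicle 1, 121 without Vehicle 2, 140 without Vehicle 4, 370 without MYCi975 4. Then it was 114 without TMP195 1, 153 without TMP195 2, 116 without TMP195 3, 132 without TMP195 4. TMP195 in H838 ran from 1 to 2943, with 37 without Vehicle 1, 24 without Vehicle 2, 29 without Vehicle 3, 208 without Vehicle 4. Then it was 209 without MYCi975 4, 21 without TMP195 1, 28 without TMP195 2, 20 without TMP195 3. TMP195 in H1703 ran from 489 to 3088, with 1179 without Vehicle 1, 1267 without Vehicle 2, 1176 without Vehicle 3, 3088 without MYCi975 4, 1312 without TMP195 1, 1242 without TMP195 4. TMP195 in H1755 ran from 4 to 353, with 39 without Vehicle 1, 38 without Vehicle 2, 52 without Vehicle 3, 47 without TMP195 1. Then it was 33 without TMP195 2, 35 without TMP195 3, 46 without TMP195 4. The combination in H838 ran from 8 to 1776, with 308 without Vehicle 1, 408 without Vehicle 2, 239 without Vehicle 3, 301 without Vehicle 4, 1518 without MYCi975 4. Then it was 435 without TMP195 3, 227 without Combo 1, 355 without Combo 3, 367 without Combo 4. The combination in H1755 ran from 25 to 1356, with 166 without Vehicle 2, 216 without Vehicle 3, 200 without Vehicle 4, 179 without Combo 1, 183 without Combo 2, 204 without Combo 3. The combination against MYCi975 in H460 ran from 0 to 1121, with 148 without Vehicle 1, 27 without MYCi975 1, 37 without MYCi975 2, 46 without MYCi975 3, 872 without MYCi975 4. Then it was 142 without TMP195 1, 44 without Combo 1, 64 without Combo 2, 98 without Combo 4. The combination against MYCi975 in H838 ran from 0 to 420, with 8 without Vehicle 4, 2 without MYCi975 1/2, Combo 1/2, 1 without MYCi975 3, Combo 3, 145 without MYCi975 4, 11 without TMP195 4, 15 without Combo 4. The combination against MYCi975 in H1703 ran from 2 to 4548, with 181 without Vehicle 1, 166 without Vehicle 2, 168 without Vehicle 3, 26 without MYCi975 1/2, 28 without MYCi975 3, 4548 without MYCi975 4, 158 without TMP195 1. Then it was 185 without TMP195 2, 192 without TMP195 3, 83 without Combo 1, 142 without Combo 2, 94 without Combo 3, 47 without Combo 4. The combination against MYCi975 in H1755 ran from 0 to 168, with 7 without Vehicle 2, MYCi975 2, TMP195 2/3, Combo 1, 2 without MYCi975 1, Combo 2, 3 without MYCi975 3, 20 without MYCi975 4. The combination against TMP195 in H460 ran from 0 to 1260, with 315 without TMP195 1, 347 without TMP195 2, 414 without TMP195 3, 501 without TMP195 4. Then it was 297 without Combo 1, 353 without Combo 2, 382 without Combo 4. The combination against TMP195 in H838 ran from 0 to 2166, with 5 without Vehicle 2, 4 without Vehicle 3, 53 without Vehicle 4, 3 without MYCi975 1, Combo 4, 15 without MYCi975 2. Then it was 117 without MYCi975 3, 378 without MYCi975 4, 0 without TMP195 1/2/3/4, Combo 1, 1 without Combo 3. The combination against TMP195 in H1703 ran from 0 to 2884, with 2719 without MYCi975 4, 163 without TMP195 1, 218 without TMP195 2, 336 without TMP195 3. Then it was 652 without Combo 1, 576 without Combo 3, 125 without Combo 4. The departure from the sum in H1703 ran from 2 to 65, with 11 without Vehicle 1, 3 without Vehicle 2/3, TMP195 1, 10 without Vehicle 4, 8 without MYCi975 1/2, Combo 4. Then it was 7 without MYCi975 3, TMP195 2/3, 57 without MYCi975 4, 13 without TMP195 4, 14 without Combo 1. The same direction in all lines with TMP195 ran from 0 to 24, with 1 without H460 Vehicle 1/2/3, H460 TMP195 1/4, H838 Vehicle 1/2/3, H838 TMP195 1/2/3, H1703 Vehicle 3, H1703 TMP195 1, H1755 Vehicle 1/2/3, H1755 TMP195 2/3. The same direction in all lines with the combination ran from 0 to 229, with 23 without H838 Vehicle 3, 24 without H838 Combo 1, H1755 Combo 2/3, 22 without H1755 Vehicle 2, 68 without H1755 MYCi975 4.

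Ranges without such a library were the combination in H460 1041 to 3614, the combination in H1703 5640 to 8699, the combination against TMP195 in H1755 0 to 4 and the departure from the sum in H838 0 to 1033. From leaving out replicate numbers only, differences between lines ran from 0 to 82 with MYCi975, 9 to 2073 with TMP195 and 502 to 3812 with the combination. Lists called ran, likewise, from 57 to 59 with MYCi975, 56 to 61 with TMP195 and 66 to 69 with the combination. In H460, H838 and H1755 the departure from the sum was 0 with edgeR without each single library. The 1033, 2943 and 2166 in H838 were without replicate 4, and read batch and TMP195 together. At this depth and spread the simulated comparison recovered 0 of 100 changes of 0.5 in H460 and 16 in H1703, so a gene not called in H460 is not shown to be unchanged.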

Other observations

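The lists and genes of the first paragraphs, the tests of departing genes and all splits of the samples were chosen or set after results were seen. Lysosome and autophagy genes were higher in H1703, with medians of 0.37 with MYCi975, 0.24 with TMP195 and 0.47 with the combination (adjusted p = 5.12e-08, 2.5e-05 and 2.52e-04; adjusted p = 0.026, 0.0687 and 0.0968 with an estimated correlation). Of 36 members, 18, 14 and 20 rose (21, 18 and 20 adjusted over the list alone). With the combination RRAGD, a GTPase of amino acid sensing at the lysosome, rose by 2.44 ± 0.35, the autophagy genes WIPI1 and MAP1LC3B by 1.54 ± 0.14 and 1.33 ± 0.18, and the protease CTSL by 1.15 ± 0.12. In H1755 the list had a median of 0.16 with MYCi975 (adjusted p = 4.86e-06; adjusted p = 0.026 with an estimated correlation), and the protease CTSD rose by 0.73 ± 0.09 with the combination. Antigen presentation genes were lower in H1703 with the combination, with a median of -0.41 (adjusted p = 0.0016; adjusted p = 0.536 with an estimated correlation); 10 of 19 fell, also adjusted over the list alone, with the immunoproteasome subunit PSMB9 at -1.85 ± 0.45, the peptidase ERAP2 at -1.82 ± 0.28 and the peptide transporter TAP1 at -1.37 ± 0.27.

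In H1755 with TMP195, hypoxia response genes had a median of 0.27 (adjusted p = 1.41e-07; adjusted p = 0.0337 with an estimated correlation). ANGPTL4, a lipase inhibitor, was the 1 of 20 members that rose, by 1.37 ± 0.16 (7 rose adjusted over the list alone). Fatty acid synthesis genes had a median of -0.18 there (adjusted p = 1.73e-05; adjusted p = 0.0206 with an estimated correlation), and fatty acid synthase, FASN, was the 1 of 15 that fell, over all genes and adjusted over the list alone, at -0.59 ± 0.10. Cytosolic ribosomal protein genes, which have many near-identical pseudogenes, were higher in H460 with the combination, with a median of 0.28 (adjusted p = 1.49e-06; adjusted p = 0.467 with an estimated correlation), and 16 of 77 rose (17 adjusted over the list alone), such as RPLP0 by 0.46 ± 0.08. In H838 with TMP195 they had a median of -0.30 (adjusted p = 1.3e-14; adjusted p = 0.23 with an estimated correlation), which was -0.13 with the batch term. None fell by edgeR over all genes there, and 35 did adjusted over the list alone.

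The 30 genes of H1703 that departed from the sum of the single-agent effects (4, 2 and 3 without replicates 1, 2 and 3) were compared with the lists by 76 Fisher's exact tests, one-sided; genes of a list are not independent, and these genes were named after their values were seen. Of 21 genes below the sum, 9 were ATF4 targets, against 0.0474 expected (Fisher's exact test, adjusted p = 7.36e-18). TRIB3 was at -1.52 (edgeR adjusted p = 8.23e-05), WARS1 at -0.99 and PCK2 at -0.98. Of 9 genes above the sum, 8 were mitotic genes, against 0.0194 expected (adjusted p = 1.68e-19), such as KIF20A at 0.82 and PLK1 at 0.75. KIF20A fell, but by less than the sum. Hypoxia genes were 2 of the lower genes (adjusted p = 0.00415).

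Each comparison of a pair of groups was refitted on its own libraries with edgeR under all 35 splits into 4 and 4, so real counts differ from those of the 16-library fits. The real count is given with the highest of the other splits in brackets. Replicate numbers were not taken to pair the samples, though pairing is not excluded, for the combination against vehicle with 2766 (336) in H460 and 7765 (0) in H1703, or against TMP195 with 688 (493) in H460 and 1533 (876) in H1703; there only the real split of 35 gave as many genes, which excludes chance only if the samples are unpaired. Numbers were taken to pair them for MYCi975 with 1113 (0) in H1703 and 1 (0) in H1755. They were also taken so for TMP195 with 531 (9) in H838, 2651 (1) in H1703 and 16 (0) in H1755. The same holds for the combination against vehicle with 609 (0) in H838 and 113 (0) in H1755, and against TMP195 with 374 (0) in H838. It holds too for TMP195 in H460 with 155, where 2 of the 35 splits were as large. Batch could give the correlations behind this as well. In H838 the batch that holds 3 of the 4 TMP195 libraries holds no vehicle or combination library, so 531 and 374 read batch and treatment together; the 16-library fits with the batch term called 66 and 5. Chance cannot be excluded for the combination against MYCi975 in H460 (13 genes, 6 splits as large) and H1703 (4, 3). Where the real split called 0 genes every split is as large, so the comparison is void. This was so, with 35 of 35, for MYCi975 in H460 and H838, the combination against MYCi975 in H838 and H1755, and the combination against TMP195 in H1755.

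Some splits gave many genes and point to the structure of the libraries. In H460 the split of replicates 1 and 2 from 3 and 4 parts the overlap-counted libraries from the others. It gave 2319 genes for MYCi975 and 2431 for TMP195, where the fits with the batch term gave 1592 and 1163. For the combination in H460 the highest other splits put the 3 overlap-counted libraries on one side and gave 336, 584 and 493 against vehicle, MYCi975 and TMP195, where the batch term gave 6685, 2301 and 3636. For the combination against MYCi975 the highest other split put all 3 second-batch libraries on one side, with 4049 genes in H1703 and 58 in H838, where the batch term gave 3001 and 76. So did the split with 876 genes for the combination against TMP195 in H1703, where the batch term gave 3845. Where replicate numbers were taken to pair the samples, only 8 splits part all pairs, too few for a share under 0.05. None of the other 7 called a gene. The real split called genes in all of these comparisons except MYCi975 in H460 and the combination against each single agent in H1755.

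For the departure from the sum, 100 groupings of the 16 libraries were drawn, the real one included. In H1703 3 were as large as the real count of 30 (highest 3755). In H460, H838 and H1755 the real count was 0, so that all 100 were as large (highest 770, 51 and 2261) and the comparison is void. For genes changed alike in all 4 lines, 100 sets of splits gave 1 as large as the real 22 for the combination (highest other 0). These sets ignore pairing. Of all 32768 that part the numbered pairs, 1 was as large (highest other 2). Other splits of H838, H1703 and H1755 called 0 genes, so agreement of lines is untested. On the 8 libraries alone MYCi975 and TMP195 each gave 0, with 100 sets as large (highest other 0), void too. For differences between lines 11 of 100 draws of the treatment labels were as large as the real 1 with MYCi975 (highest other 1148), so chance cannot be excluded. With TMP195 4 reached the real 255 (highest other 1148) and with the combination 1 reached 2163 (highest other 1278). Draws for the departure and for line differences ignore pairing and undo all treatment effects, so they test neither the sum nor a shared response.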
